A study of Homo sapiens with 8 samples.

How the data were processed

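RNA of the H358 line was measured on 8 Affymetrix U133-2 arrays, 1 per condition. Per the labels, total RNA was extracted and its quality checked, labelled as biotinylated cRNA and hybridised, and the cells grew with 10% serum in the versions named vector, Snail, Zeb1 and TGFbeta. The dose of 0.5 µg/ml doxycycline stands in the labels of every array, and the arrays were taken as treated only where the title and the sample's own treatment entry say so. The TGFbeta isoform, the length of induction and whether the arrays come from separate cultures are not given in the labels.

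The values deposited by the authors are probe set intensity on a linear scale. The summary algorithm, the background correction and the scaling are not given in the sources used here. The mean over all probe sets after trimming 2% at each end lay between 250.02 and 250.03 on every array, so the deposited values share a linear scaling to that mean. GAPDH probe sets at the 3′ and 5′ ends had intensity ratios from 0.882 to 0.937 and ACTB probe sets from 1.18 to 1.39. Median intensity lay between 65.1 and 74.01. For arrays no read depth exists, and their number limits the precision.

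Values below 1, of which there were 156 to 298 per array, were set to 1. All values were then taken as log2 and quantile normalized across the 8 arrays. Fold changes of dim genes depend on this floor. Probe sets were matched to genes by the gene table of the array and a RefSeq gene table, used for current names only. Of the probe sets, 41097 had a single gene symbol (41043 with the symbol updated by gene identifier and 54 with the older symbol kept), 1801 had several and 11777 had none, and the last 2 kinds were left out of the gene-level tests. A probe set was kept if it lay above the median of all probe sets of the array on at least 1 array, and each gene was represented by its kept probe set with the highest mean. This left 14597 of 19775 genes. Genome positions were not used here.

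All tests used limma 3.58.1 in R 4.3.3 (linear fit, moderated test, two-sided), with Benjamini-Hochberg adjustment over the 14597 genes and a threshold of 0.05. The shared response compared the mean of the 3 induced arrays with the mean of the 5 arrays with no induced driver, Vector Dox included. Each driver was tested in a fit of 4 means, the reference and each induced array, and the differences between drivers came from the same fit. A lone array is thereby assumed to vary like the 5 uninduced arrays, whose spread gives 4 residual degrees of freedom and holds differences between lines and between Vector Dox and the rest. No label says that the arrays are separate cultures, so each p measures a difference against the spread among these arrays, which may be technical. The number of called genes on the same side of the driver's own line without doxycycline is given beside each test. Doxycycline in the vector line and the lines without doxycycline were compared by size only, as the number of genes at least 2-fold apart. Error values are standard errors of the fit (SE) unless given as SD.

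Gene lists were tested with camera of limma at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 16 lists within each comparison. List medians in a line against itself were ranked among 10000 random lists of the same size matched on mean expression. Random lists do not keep the correlation among the genes of a list, so an extreme rank is not a test. Genes were named by rule: SNAI1, ZEB1, the TGFbeta isoforms, CDH1 and VIM always; in the shared response the 12 largest rises and 12 largest falls with all 3 induced arrays at least 2-fold from their own lines on that side; for each driver the 10 largest each way at least 2-fold from its own line; for each pair of drivers the 5 largest differences each way; for the vector line the 3 largest each way; and up to 2 rises and 2 falls per list and driver. CSF1R, the only call in its list, and the members of gene families in the closing part were named after their values were seen. The lists, the tests, the filter and the naming rule were chosen before the data were examined.

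Tested on simulated data with 14597 genes, 200 of them changed, in 10 runs, the shared test recovered 57.6% of genes changed 2-fold and 93.8% of those changed 4-fold, with 5.28% of calls false. For Snail, Zeb1 and TGFbeta the tests recovered 9.8%, 9.2% and 9.2% at 2-fold and 75.2%, 73.6% and 75.8% at 4-fold, with 6.48%, 5.07% and 5.63% of calls false. The simulated arrays had independent normal noise of the fitted spread, no differences between lines, and the same change with each driver. These shares hold for that setting and may not hold for the real arrays. Alternatives were no filter and a filter at the 75th percentile, the mean of a gene's probe sets, probe sets tested singly, median centring, deposited scaling, log2 of the value plus 16, a variance trend with robust fit, an adjusted p under 0.01, limma's treat against 1.5-fold, the line as a block, and leaving out arrays in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The RT-PCR that the series text mentions was not used here.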

Results

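H358 is an established human non-small cell lung cancer cell line that carries a mutant KRAS gene. It was used here in 4 versions that switch on Snail, Zeb1, TGFbeta or an empty vector when the antibiotic doxycycline is added. Snail (gene SNAI1) and Zeb1 are transcription factors that repress epithelial genes, and TGFbeta is a secreted growth factor. Each of them can start epithelial-mesenchymal transition, in which cells of an epithelial sheet lose their junctions and take on features of motile mesenchymal cells, and the comparisons ask which transcripts follow each driver. Each version was measured once without doxycycline and once with 0.5 µg/ml of it, so each of the 8 conditions is a single array. From the probe sets of the arrays 14597 named genes were tested. The median intensity per array lay between 65.1 (TGFbeta) and 74.01 (Zeb1), and the number of arrays, not a read depth, limits the precision. With 1 array per condition, no driver's response has a replicate check. The arrays are called Vector, Snail, Zeb1 and TGFbeta without doxycycline, and Vector Dox, Snail Dox, Zeb1 Dox and TGFbeta Dox with it. The 5 arrays with no induced driver, Vector Dox included, are the reference of each test.

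The driver genes were read first, as a check of the labels. SNAI1 had an intensity of 647 on the Snail Dox array against 127 on the Snail array, but it was as high on the Zeb1 Dox array, at 675, and on the TGFbeta Dox array, at 638. On the 5 reference arrays it averaged 169 ± 54.4 (SD, n = 5). ZEB1 behaved alike, with 258, 231 and 231 on the Snail Dox, Zeb1 Dox and TGFbeta Dox arrays against 34.3 ± 9.27 on the reference arrays (SD, n = 5). It rose with Snail by 2.97 (log2; adjusted p = 0.0101), with Zeb1 by 2.80 (adjusted p = 0.0111) and with TGFbeta by 2.84 (adjusted p = 0.0105), although another of its probe sets gave -0.68 with Snail. SNAI1 rose with TGFbeta by 2.00 (adjusted p = 0.0438). With Snail its difference was 1.98 (adjusted p = 0.0608) and with Zeb1 2.04 (adjusted p = 0.0542), neither of which passed. The levels of SNAI1 and ZEB1 therefore set the 3 induced arrays apart from the rest but not from each other. A transgene without the natural 3′ end of its gene would be missed by these probe sets, so they do not settle which driver each array holds.

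The label TGFbeta names no isoform. TGFB1 read 1622 and 1544 on the Snail Dox and Zeb1 Dox arrays and 641 on the TGFbeta Dox array, against a mean of 477 ± 136 on the reference arrays (SD, n = 5), and passed the test with none of the drivers. TGFB2 rose with Snail by 1.496 (log2; adjusted p = 0.0286), with Zeb1 by 1.46 (adjusted p = 0.0284) and with TGFbeta by 2.11 (adjusted p = 0.00905). TGFB3 differed by 0.78, 0.37 and 0.07 and did not pass, and against each driver's own line it differed by 0.62, 0.55 and 0.51. CDH1, the gene of the junction protein E-cadherin, fell with Snail (-2.10; adjusted p = 0.00985) and with Zeb1 (-2.21; adjusted p = 0.00764). With TGFbeta its difference was -0.003 ± 0.24 (SE; adjusted p = 0.995), and against the TGFbeta line without doxycycline it was -0.33. VIM, the gene of the mesenchymal filament protein vimentin, rose with TGFbeta by 1.80 (adjusted p = 0.0357), and its differences of 1.41 with Snail and 1.47 with Zeb1 did not pass (adjusted p = 0.0911 and 0.0766).

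**Figure D1:**
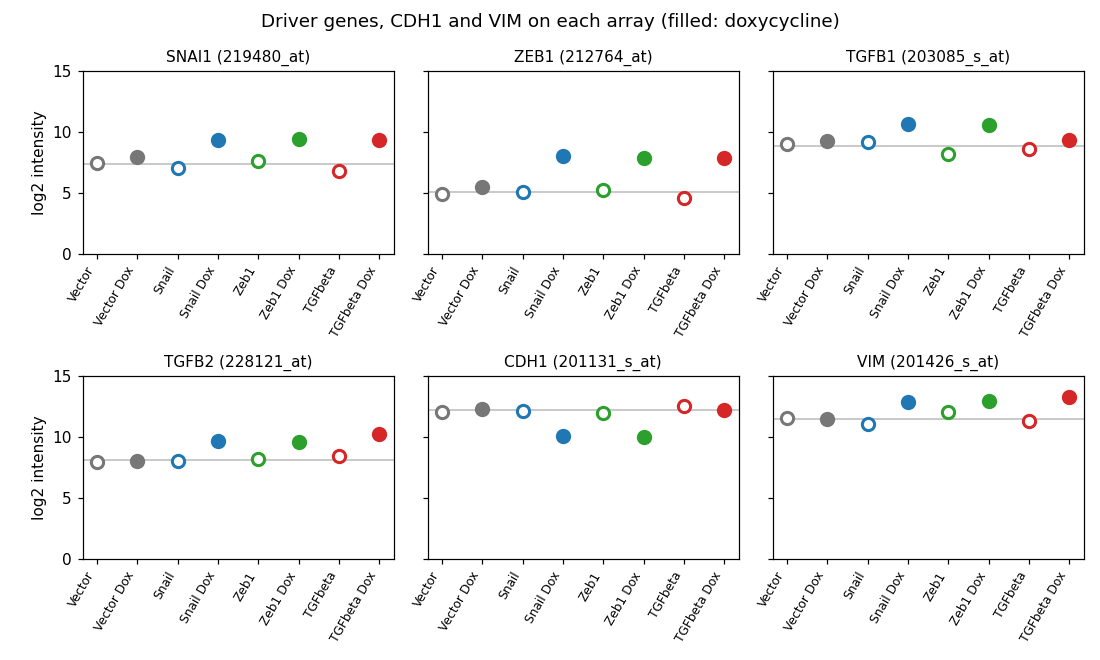
Normalized log2 intensity of 6 genes on each of the 8 arrays, 1 point per array, filled with doxycycline and open without it. The grey line is the mean of the 5 arrays with no induced driver. SNAI1 and ZEB1 are high on all 3 induced arrays, while CDH1 is low on the Snail Dox and Zeb1 Dox arrays and stays near the line on the TGFbeta Dox array.

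Doxycycline in the vector line served as the control for the antibiotic itself. The genes that differed most by size between Vector Dox and Vector were MAF (log2 difference 4.09), MYPN (3.80) and ZEB2 (3.58), which were higher, and TMEM253 (-4.21), NAP1L3 (-4.11) and SHISA7 (-3.78), which were lower. These 6 genes were dim, and their SD over the 5 reference arrays ran from 1.62 (ZEB2) to 2.42 (MAF). In all, 735 genes lay at least 2-fold apart, 359 higher and 376 lower, against 2013 genes in the Snail line, 2416 in the Zeb1 line and 2319 in the TGFbeta line. Among the 7837 genes with a mean log2 intensity over 8, the vector line had 10 such genes and the driver lines 613, 740 and 767. The cell cycle genes were the gene list that moved most with doxycycline in the vector line, with a median difference of -0.39 that was below the median of each of 10000 random lists of like intensity. The other 15 lists had medians from -0.07 to 0.15. These differences were not tested.

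Before induction the driver lines already differed from the vector line. Without doxycycline, 932 genes lay at least 2-fold apart between Snail and Vector, 1220 between Zeb1 and Vector and 1121 between TGFbeta and Vector. Among the brighter genes these numbers were 51, 110 and 100. The Snail and Zeb1 arrays lay furthest apart without doxycycline, with 233 brighter genes at least 2-fold apart. Each line is 1 array here, so a difference between lines cannot be told from that of an unusual array or culture. On the Zeb1 array the hybridisation controls stood at 1.90 times the median of the other arrays. These differences were not tested, and they are part of the spread of the reference arrays.

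The shared response compared the 3 induced arrays with the 5 reference arrays. The largest rises were of SPARC, a collagen-binding matrix protein, by 5.90 ± 0.66 (log2, SE; adjusted p = 0.00202), the protease ADAMTS1 by 4.93, the cytokine IL11 by 3.97, LRRC32, which tethers TGF-beta to the cell surface, by 3.90, the matrix protein thrombospondin (THBS1) by 3.63 and the growth factor receptor PDGFRA by 3.51. PLEKHO1 rose by 3.91, IL32 by 3.64, MIR181A2HG by 3.63, PRSS33 by 3.61, APCDD1L by 3.58 and IGFBP7 by 3.38. The largest falls were of GOLT1A (-5.75 ± 0.22, SE; adjusted p = 4.04e-05), ADIRF (-4.83), the airway mucin MUC5B (-4.58), the ion transport regulator FXYD3 (-4.51), the sialyltransferase ST6GALNAC1 (-4.19) and the tight junction protein CLDN3 (-3.80). The calcium-binding proteins S100A5 (-4.12) and S100P (-3.72) also fell, as did CFD (-3.98), INHBB (-3.98), FAM201A (-3.83) and DNAH2 (-3.70). Several of the genes that fell are dim on the induced arrays. Several that rose are dim on the reference arrays, such as IL32 (mean log2 intensity 2.41) and PLEKHO1 (2.71). The sizes and order of both depend on the floor, and with an offset of 16 GOLT1A was -3.24. Without the filter on dim probe sets, other probe sets stand for PDGFRA and FAM201A, and their differences were -0.79 and 0.06. Another FXYD3 probe set gave -0.32, another MUC5B probe set -2.145, and the probe sets of THBS1 ran from 0.29 to 4.59.

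Of the 14597 genes, 579 rose and 854 fell in the shared response, 1433 in all, and 3665 had an unadjusted p under 0.05 where chance gives 730. The test takes the 3 induced arrays as separate. As given below, it stays open whether the Snail Dox and Zeb1 Dox arrays hold separate RNA or separate lines. If they do not, the spread among induced arrays is understated and the count may be too high. The 3 induced arrays lay on the called side of their own lines without doxycycline for 1432 of the 1433 genes, and each by at least 2-fold for 402 of them. The own lines are among the reference arrays, so the call itself largely sets the side, here and for each driver below. CDH1 did not pass here, with a difference of -1.44 (adjusted p = 0.0983), and without the TGFbeta Dox array it fell by 2.16 (adjusted p = 0.000483). The count was 605 without Snail Dox, 618 without Zeb1 Dox, 815 without Vector Dox, 848 without Vector, 924 without Snail and 885 without the filter on dim probe sets. With the line as a block, 663 genes passed over all 8 arrays, 584 of them among the 1433, and limma called 0 over the 6 arrays of the driver lines, where 2693 genes had an unadjusted p under 0.05.

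Many genes of the epithelial lists fell in the shared response and many matrix genes rose, while others did not pass. Of 24 measured junction and polarity genes, 0 rose and 12 fell (0 and 16 adjusted over the list alone), CLDN3 among them, with adjusted p = 2.62e-10 for the list and adjusted p = 0.156 with an estimated correlation. Of 27 genes of epithelial keratins and identity, 0 rose and 19 fell (0 and 23 adjusted over the list alone), such as the membrane protease TMPRSS4 (-3.65), with adjusted p = 1.32e-16 and adjusted p = 0.0752 with an estimated correlation. Of 15 lung lineage genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone), such as AGR2 (-3.11), which helps fold mucins, with adjusted p = 1.43e-05 and adjusted p = 0.0217 with an estimated correlation. Of 28 genes of matrix proteins and proteases, 15 rose and 0 fell (20 and 0 adjusted over the list alone), with adjusted p = 3.04e-12 and adjusted p = 0.00286 with an estimated correlation. Of 22 genes of the mesenchymal cytoskeleton and adhesion, 5 rose and 0 fell (9 and 0 adjusted over the list alone), VIM among them by 1.56 ± 0.22 (SE; adjusted p = 0.00503). That list had adjusted p = 0.000426, and adjusted p = 0.0596 with an estimated correlation. Of 9 transcription factors known to drive the transition, 5 rose and 0 fell (6 and 0 adjusted over the list alone), SNAI1 by 2.01 ± 0.25 (SE; adjusted p = 0.00289) and ZEB1 by 2.87 among them. That list had adjusted p = 4.43e-05 and adjusted p = 0.0596 with an estimated correlation. SNAI1 and ZEB1 are drivers themselves, so their rises on the arrays of their own lines may be the transgenes. The list was not tested without them.

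Signalling lists moved less evenly in the shared response. Of 16 targets of YAP and TEAD, which relay cell shape and contact to the nucleus, 8 rose and 0 fell (12 and 0 adjusted over the list alone), such as AMOTL2 by 1.15 and AJUBA by 1.39, with adjusted p = 4.19e-07 and adjusted p = 0.0373 with an estimated correlation. Of 20 TGF-beta and SMAD targets, 3 rose and 0 fell (6 and 0 adjusted over the list alone), with adjusted p = 0.000561 and adjusted p = 0.0752 with an estimated correlation. Of 17 cytokine and NF-kB genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone), IL11 and IL32 among the rises, with adjusted p = 0.00185 and adjusted p = 0.115 with an estimated correlation. Of 20 genes of the integrated stress response, 3 rose and 0 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.000561 and adjusted p = 0.416 with an estimated correlation. Of 26 cell cycle genes, 0 rose and 2 fell (the same numbers adjusted over the list alone), with a list median of -0.54, adjusted p = 0.00011 and adjusted p = 0.416 with an estimated correlation. Against the own line without doxycycline the cell cycle median was 0.05 with Snail, -0.64 with Zeb1 and -0.97 with TGFbeta, and -0.39 in the vector line, where no driver is induced. Of 25 receptor tyrosine kinases, 2 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.367), and of 23 growth factor ligands 2 rose and 2 fell (the same numbers adjusted over the list alone; list adjusted p = 0.213). Of 17 hypoxia and glycolysis genes, 1 fell (0 adjusted over the list alone; list adjusted p = 0.157), and of 24 interferon and antigen presentation genes, 0 passed over all genes (list adjusted p = 0.995). Among 10 blood and endothelial cell markers 1 rose, CSF1R by 1.41, and the list did not pass (adjusted p = 0.615).

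**Figure D2:**
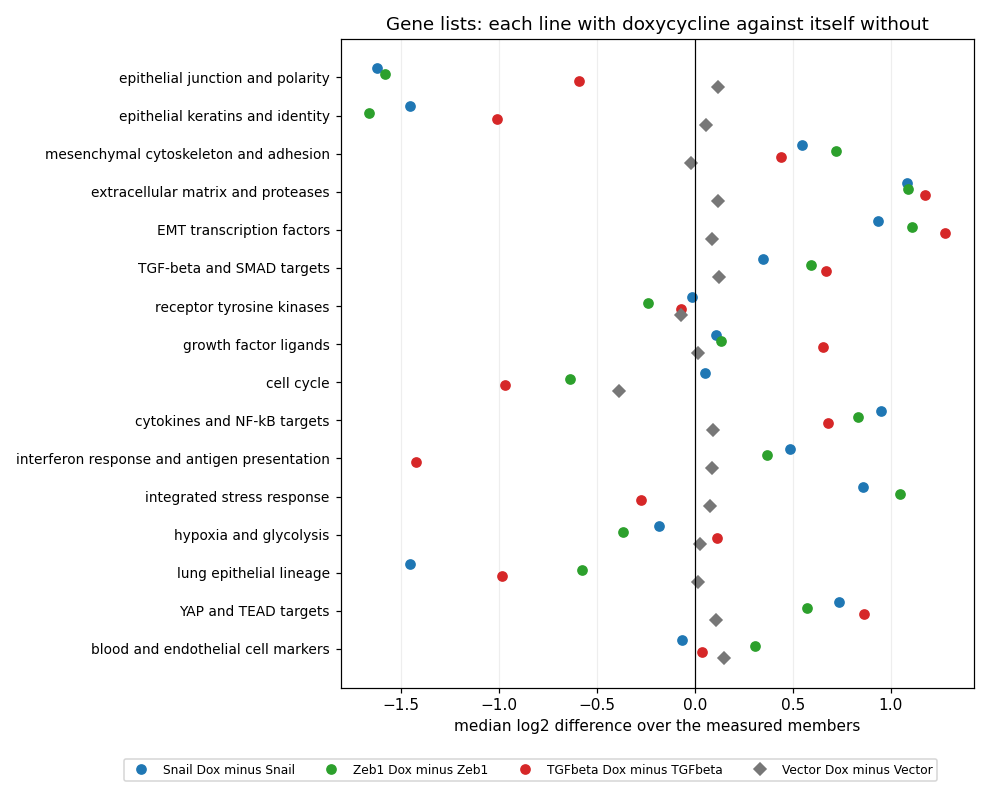
Median log2 difference of each gene list between a line with doxycycline and the same line without it, 1 point per list and line. The interferon list is below 0 in the TGFbeta line, at -1.43, and above 0 in the Snail and Zeb1 lines, while the vector line stays between -0.39 and 0.15.

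Snail was tested as the Snail Dox array against the 5 reference arrays, to ask what this repressor changes. The largest rises were of SPARC by 6.87 ± 0.58 (log2, SE; adjusted p = 0.00536), the neuropeptide gene NPW by 5.93, ARC by 4.18, IGFBP7 by 3.95, PLEKHO1 by 3.68, PRSS33 by 3.51, MIR181A2HG by 3.45, the collagenase MMP13 by 3.44, IL32 by 3.36 and the thrombin receptor F2R by 3.24. The largest falls were of GOLT1A (-5.92), FXYD3 (-5.28 ± 0.35, SE; adjusted p = 0.00344), the orphan receptor GPR160 (-5.25 ± 0.17, SE; adjusted p = 0.000761), ADIRF (-5.07), TTC9 (-5.02), the fructose kinase KHK (-4.93), the mucins MUC16 (-4.64) and MUC5B (-4.31), ICA1-AS1 (-4.35) and ST6GALNAC1 (-4.33). These genes are dim on the Snail Dox array, GOLT1A at a log2 intensity of 1.43, so the sizes and order of the falls depend on the floor, and with an offset of 16 GOLT1A was -3.26. Another FXYD3 probe set gave -0.505, and another MUC5B probe set -0.754. Of the rises, ARC and IL32 were dim on the reference arrays, at mean log2 intensities of 2.09 and 2.41. NPW was near the floor on the reference arrays, at a mean log2 intensity of 0.39, so the size of its rise depends on the floor, and with an offset of 16 it was 2.46. With a variance trend and robust fit NPW did not pass (adjusted p = 0.506). In all 180 genes rose and 420 fell, 600 together, and 2773 had an unadjusted p under 0.05 where chance gives 730. The 600 genes lay on the called side of the Snail line without doxycycline, 553 of them by at least 2-fold. Without Vector Dox 270 genes passed, without Vector 278, without Snail 348 and without the filter on dim probe sets 291, while 983 passed with the filter at the 75th percentile and 1080 with a variance trend and robust fit.

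Many junction genes fell with Snail. Of the 24, 0 rose and 14 fell (0 and 21 adjusted over the list alone), the tight junction genes CLDN3 (-4.08) and CLDN4 (-3.08) most, with adjusted p = 2.16e-19 for the list and adjusted p = 0.0462 with an estimated correlation. Among the 27 epithelial keratins and identity genes 0 rose and 16 fell (0 and 25 adjusted over the list alone), FXYD3 and TMPRSS4 (-3.28) most, with adjusted p = 5.58e-24 and adjusted p = 0.0416 with an estimated correlation. Lung lineage genes fell in 4 of 15 cases and rose in 0 (6 and 0 adjusted over the list alone), AGR2 (-3.03), with adjusted p = 1.92e-05 and adjusted p = 0.0416 with an estimated correlation. Matrix and protease genes rose in 8 of 28 cases and fell in 0 (13 and 0 adjusted over the list alone), the collagen gene COL3A1 by 3.21, with adjusted p = 6.46e-10 and adjusted p = 0.0306 with an estimated correlation. Of the 22 mesenchymal genes 0 passed over all genes (5 rose and 0 fell adjusted over the list alone), and limma gave adjusted p = 0.0028 for the list and adjusted p = 0.0524 with an estimated correlation. Among the 9 transcription factors 2 rose, ZEB1 and TCF4 (by 1.03), and 0 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.000237 and adjusted p = 0.0462 with an estimated correlation. That list holds SNAI1, the driver itself, and was not tested without it.

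Some stress and cytokine genes also rose with Snail, most members not passing singly. Of the 20 integrated stress response genes 2 rose and 0 fell (10 and 0 adjusted over the list alone), the glutathione-degrading enzyme CHAC1 by 2.74 and asparagine synthetase ASNS by 1.54, with adjusted p = 1.8e-07 and adjusted p = 0.0416 with an estimated correlation. Of the 17 cytokine genes 4 rose and 1 fell (7 and 2 adjusted over the list alone), IL11 rose by 2.92 and TNFAIP2 fell by 1.41, with adjusted p = 0.000899 and adjusted p = 0.0462 with an estimated correlation. Among the 24 interferon genes 1 rose, IFI44L by 1.48, and 0 fell (6 and 0 adjusted over the list alone), with adjusted p = 0.000883 and adjusted p = 0.136 with an estimated correlation. YAP and TEAD targets rose in 2 of 16 cases, AJUBA by 1.57 and AMOTL2 by 1.20 (8 adjusted over the list alone), with adjusted p = 0.000144 and adjusted p = 0.082 with an estimated correlation. Of the 20 TGF-beta and SMAD targets 2 rose, ID3 by 2.14 and LTBP2 by 1.21, and 0 fell (the same numbers adjusted over the list alone), with adjusted p = 0.00324 and adjusted p = 0.106 with an estimated correlation. Hypoxia and glycolysis genes had 1 fall in 17, the enolase ENO2 (-1.93) (5 adjusted over the list alone), with adjusted p = 0.00762 and adjusted p = 0.228 with an estimated correlation. The receptor AXL rose by 3.08, and the receptors MST1R and ERBB3 fell by 2.16 and 2.05, as 1 rise and 3 falls among 25 receptor tyrosine kinases (2 and 6 adjusted over the list alone; list adjusted p = 0.208), whose median was -0.04 and mean 0.04. Another probe set of ERBB3 gave 0.15, and another of LTBP2 -0.16. Among 23 ligands FGF1 fell by 2.13 (1 rise and 3 falls adjusted over the list alone; list adjusted p = 0.635), with a median of 0.12 and a mean of -0.12, and another FGF1 probe set gave 0.90. With an offset of 16 FGF1 did not pass (adjusted p = 0.0575). Among 26 cell cycle genes CCND1, the gene of cyclin D1, fell by 2.25 (1 fall adjusted over the list alone as well; list adjusted p = 0.0939). None of the 10 blood and endothelial markers passed (adjusted p = 0.924).

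Zeb1 was tested in the same way, as the Zeb1 Dox array against the reference arrays. SPARC rose by 6.73 ± 0.58 (log2, SE; adjusted p = 0.0048), NPW by 6.42, which was 2.88 with an offset of 16 and did not pass with a variance trend and robust fit (adjusted p = 0.464), IL32 by 4.91 ± 0.25 (SE; adjusted p = 0.00212), ARC by 4.63, PLEKHO1 by 4.06, IGFBP7 by 3.77, F2R by 3.32, the motor protein gene KIF21B by 3.29, MIR181A2HG by 3.26 and PRSS33 by 3.24. The largest falls were of FAM201A (-5.68), TTC9 (-5.68), GOLT1A (-5.63), ADIRF (-5.58), C2orf15 (-5.22), FXYD3 (-5.21), CLDN3 (-4.88 ± 0.34, SE; adjusted p = 0.00276), S100A5 (-4.56), the tight junction gene MARVELD3 (-4.48) and CFD (-4.28). Another FXYD3 probe set gave -0.033. Of the rises, ARC and IL32 were dim on the reference arrays, at mean log2 intensities of 2.09 and 2.41. The genes with the largest falls are dim on the Zeb1 Dox array, down to a log2 intensity of 0.33 for FAM201A and 1.72 for GOLT1A. The sizes and order of the falls thus depend on the floor. With an offset of 16 FAM201A was -2.23 and GOLT1A -3.22. C2orf15 was at the floor there, and with the offset it was -1.68 and did not pass (adjusted p = 0.141). In all 162 genes rose and 481 fell, 643 together, and 2814 had an unadjusted p under 0.05. Each of the 643 lay on the called side of the Zeb1 line without doxycycline, 573 by at least 2-fold. Leaving out Vector Dox left 340 genes, Vector 348 and Snail 379, and dropping the filter on dim probe sets left 381, while 1089 passed with a variance trend and robust fit.

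With Zeb1, 14 of the 24 junction genes fell and 0 rose (20 and 0 adjusted over the list alone), with adjusted p = 1.55e-18 and adjusted p = 0.0581 with an estimated correlation. Epithelial keratins and identity genes fell in 20 of 27 cases and rose in 0 (24 and 0 adjusted over the list alone), TMPRSS4 (-4.06), with adjusted p = 2.93e-23 and adjusted p = 0.0439 with an estimated correlation. The lung lineage list had 3 falls and 0 rises among 15 (5 and 0 adjusted over the list alone), AGR2 (-3.14) and MUC5B (-2.98), with adjusted p = 7.02e-05 and adjusted p = 0.0439 with an estimated correlation. Matrix and protease genes had 7 rises and 0 falls among 28 (13 and 1 adjusted over the list alone), COL3A1 by 2.65, with adjusted p = 2.99e-09 and adjusted p = 0.0352 with an estimated correlation. None of the 22 mesenchymal genes passed in limma over all genes (6 rose and 0 fell adjusted over the list alone), and the list had adjusted p = 0.00421 and adjusted p = 0.0612 with an estimated correlation. Of the 9 transcription factors 2 rose, ZEB1 and TCF4 (by 1.22), and 0 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.00277 and adjusted p = 0.0612 with an estimated correlation. ZEB1 is the driver itself here, and the list was not tested without it.

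Integrated stress response genes had 3 rises and 0 falls among 20 with Zeb1 (12 and 0 adjusted over the list alone), CHAC1 by 2.66 and ASNS by 1.66, with adjusted p = 1.49e-07 and adjusted p = 0.0439 with an estimated correlation. Cytokine genes had 5 rises and 1 fall among 17 (7 and 2 adjusted over the list alone), IL11 rose by 3.11 and TNFAIP2 fell by 1.35, with adjusted p = 0.000463 and adjusted p = 0.0515 with an estimated correlation. YAP and TEAD targets had 2 rises among 16, AJUBA by 1.66 and AMOTL2 by 1.25 (6 adjusted over the list alone), with adjusted p = 2.99e-05 and adjusted p = 0.0623 with an estimated correlation. The TGF-beta and SMAD list had 1 rise among 20, ID3 by 1.95 (2 adjusted over the list alone), with adjusted p = 0.00172 and adjusted p = 0.0839 with an estimated correlation. The interferon list had 0 calls among 24 genes, over all genes and adjusted over the list alone, and adjusted p = 0.00284 upward, or adjusted p = 0.179 with an estimated correlation. Hypoxia and glycolysis genes had 2 falls among 17, ENO2 (-1.66) and the hexokinase HK2 (-1.27) (3 adjusted over the list alone), with adjusted p = 0.00913 and adjusted p = 0.238 with an estimated correlation. AXL rose by 3.17, and ERBB3 and MST1R fell by 2.15 and 2.01, as 1 rise and 3 falls among 25 receptor tyrosine kinases (2 and 5 adjusted over the list alone; list adjusted p = 0.21), with a median of -0.09 and a mean of 0.002, and another ERBB3 probe set gave 0.16. Of 23 ligands 0 passed over all genes (1 rise and 1 fall adjusted over the list alone; list adjusted p = 0.742), with a median of 0.14 and a mean of -0.004. CCND1 fell by 2.16 as the 1 call among 26 cell cycle genes, also adjusted over the list alone (list adjusted p = 0.0506), and 0 of the 10 blood and endothelial markers passed (list adjusted p = 0.411).

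Snail and Zeb1 gave similar arrays, most of all among the brighter genes. SPARC lay at a log2 intensity of 13.54 on the Snail Dox array and 13.40 on the Zeb1 Dox array, CDH1 at 10.10 and 10.00, and VIM at 12.89 and 12.96. Across the 7837 genes with a mean log2 intensity over 8, their correlation was 0.988 with an SD of the difference of 0.20 (log2), and 11 genes lay at least 2-fold apart. The Vector and Vector Dox arrays had 0.984, 0.22 and 10, while the Snail and Zeb1 lines without doxycycline had 0.945, 0.41 and 233. Over all 14597 genes, dim ones included, the Snail Dox and Zeb1 Dox arrays had a correlation of 0.971 and 715 genes at least 2-fold apart, against 0.968 and 735 for the Vector and Vector Dox arrays. Among the named genes Snail minus Zeb1 was 4.31 for C2orf15 (adjusted p = 0.751), -2.82 for GPR160 (adjusted p = 0.0658), -2.29 for FGF1, -2.26 for KHK and 1.84 for MARVELD3, none of which passed. In limma, 0 genes differed between Snail and Zeb1, and 417 had an unadjusted p under 0.05 where chance gives 730, and 1 gene passed with the filter at the 75th percentile. None of the 16 gene lists differed between them, the lowest adjusted p being 0.496. These are 1 array against 1, and differences of the size given above did not pass. The test could thus miss large differences as well as small ones.

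TGFbeta was tested as the TGFbeta Dox array against the reference arrays. The largest rises were of ADAMTS1 by 5.90 ± 1.28 (log2, SE; adjusted p = 0.0482), IL11 by 5.89 ± 0.45 (SE; adjusted p = 0.00341), APCDD1L by 5.31, THBS1 by 4.81, LRRN1 by 4.74, RASGEF1C by 4.66, the Wnt ligand WNT5B by 4.56, LRRC32 by 4.55, the receptor GPR17 by 4.43 and ODAPH by 4.30. The largest falls were of MUC5B (-6.45 ± 0.42, SE; adjusted p = 0.00314), GOLT1A (-5.69), EVI2B (-5.52 ± 0.23, SE; adjusted p = 0.00141), LINC01091 (-5.49), TMCO4 (-4.85), ST6GALNAC1 (-4.73), SECTM1 (-4.56), INHBB (-4.56), the interferon-induced protease USP18 (-4.52) and the adhesion receptor ADGRF1 (-4.43). Of the rises, GPR17, WNT5B and APCDD1L were dim on the reference arrays, at mean log2 intensities of 1.905, 2.08 and 2.89. The sizes and order of the rises thus depend on the floor. Probe sets of THBS1 ran from 0.725 to 6.67, and another MUC5B probe set gave -2.28. Most of the genes with the largest falls are dim on the TGFbeta Dox array, EVI2B at a log2 intensity of 0.41 and LINC01091 at 0.55. The sizes and order of the falls therefore depend on the floor as well. With an offset of 16 EVI2B was -2.15, and LINC01091 was -2.30 and did not pass (adjusted p = 0.144). In all 379 genes rose and 640 fell, 1019 together, and 3335 had an unadjusted p under 0.05. The 1019 genes were on the called side of the TGFbeta line without doxycycline, 852 of them by at least 2-fold. Without Vector Dox 512 genes passed, without Vector 529, without Snail 584 and without the filter on dim probe sets 496, while 1628 passed with a variance trend and robust fit.

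Some interferon and antigen presentation genes fell with TGFbeta. Of the 24, 0 rose, 9 fell and 15 did not pass (1 and 16 adjusted over the list alone), the antiviral enzyme OAS1 (-2.69) and the immunoproteasome subunit PSMB9 (-2.48), with a list median of -1.11, adjusted p = 6.72e-08 and adjusted p = 0.0524 with an estimated correlation, which does not pass. Against the TGFbeta line without doxycycline the list's median was -1.43, below that of each of 10000 random lists of like intensity. The medians of the epithelial keratins and identity (-1.01), cell cycle (-0.97) and lung lineage (-0.99) lists also lay below those of all their random lists. The rank therefore does not single out the interferon list. Cell cycle genes had 8 falls and 0 rises among 26 (11 and 0 adjusted over the list alone), RRM2 of nucleotide synthesis (-1.64) and the replication gene MCM4 (-1.19), with adjusted p = 1.84e-08 and adjusted p = 0.216 with an estimated correlation. In the vector line these genes had a median difference of -0.39 with doxycycline. Growth factor ligands had 8 rises and 1 fall among 23 (14 and 3 adjusted over the list alone), WNT5B and the platelet-derived growth factor PDGFA (by 2.79) rose and EREG fell by 1.75, with adjusted p = 3.76e-05 and adjusted p = 0.0524 with an estimated correlation. TGF-beta and SMAD targets had 5 rises and 1 fall among 20 (12 and 2 adjusted over the list alone), with adjusted p = 5.16e-05 and adjusted p = 0.0524 with an estimated correlation. Of these, the feedback regulator PMEPA1 rose by 3.86 and LTBP2, which binds matrix and is related to proteins that store TGF-beta, by 3.48, while ID3, an inhibitor of helix-loop-helix factors, fell by 1.89.

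Matrix and protease genes had 11 rises and 0 falls among 28 with TGFbeta (14 and 0 adjusted over the list alone), THBS1 and SPARC (by 4.09) most, with adjusted p = 4.26e-11 and adjusted p = 0.0224 with an estimated correlation. Mesenchymal genes had 6 rises and 0 falls among 22 (7 and 0 adjusted over the list alone), N-cadherin (CDH2) by 2.44 and tropomyosin (TPM1) by 1.88, with adjusted p = 0.000231 and adjusted p = 0.0524 with an estimated correlation. The 9 transcription factors had 4 rises, SNAI2 by 2.35, and 0 falls (5 and 0 adjusted over the list alone), with adjusted p = 2.96e-05 and adjusted p = 0.0524 with an estimated correlation. YAP and TEAD targets had 5 rises and 0 falls among 16 (11 and 1 adjusted over the list alone), PTPN14 by 1.83 and GADD45B by 1.67, with adjusted p = 3.86e-07 and adjusted p = 0.0524 with an estimated correlation. Junction genes went both ways, with 2 rises and 6 falls among 24 (2 and 11 adjusted over the list alone): DSC2 and TJP1 rose by 1.27 and 1.03, and MARVELD3 and TJP3 fell by 2.89 and 2.80. That list had adjusted p = 0.00534 and adjusted p = 0.407 with an estimated correlation. Epithelial keratins and identity genes had 9 falls and 0 rises among 27 (10 and 1 adjusted over the list alone), TMPRSS4 (-3.60) and the epithelial transcription factor EHF (-3.09), with adjusted p = 1.61e-06 and adjusted p = 0.164 with an estimated correlation. Lung lineage genes had 4 falls and 0 rises among 15 (5 and 0 adjusted over the list alone), FOXA2, a transcription factor of lung epithelium of which another probe set gave 0.11, fell by 3.44, with adjusted p = 0.00202 and adjusted p = 0.0524 with an estimated correlation.

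Cytokine genes had 4 rises and 1 fall among 17 with TGFbeta (4 and 3 adjusted over the list alone; list adjusted p = 0.0959), IL11 and IL32 rising and CXCL8 falling by 2.13. Among 20 integrated stress response genes GDF15 fell by 3.15 and the cystine transporter SLC7A11 (-1.55), and 0 rose (4 falls adjusted over the list alone; list adjusted p = 0.482). Among 25 receptor tyrosine kinases FGFR3 fell by 2.39 and ERBB3 (-2.09) (3 rises and 6 falls adjusted over the list alone; list adjusted p = 0.768), with a median of 0.06 and a mean of -0.07, and another ERBB3 probe set gave 0.41. Of 17 hypoxia and glycolysis genes and 10 blood and endothelial markers 0 passed over all genes (list adjusted p = 0.321 and adjusted p = 0.652).

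The last comparisons asked where TGFbeta differed from the transcription factors. CDH1 was lower by a log2 difference of -2.10 with Snail than with TGFbeta (adjusted p = 0.0437) and of -2.21 with Zeb1 (adjusted p = 0.0358). Against TGFbeta, Snail and Zeb1 gave higher levels of NPW (6.31 and 6.80), the pseudogene ZDHHC8BP (5.66 and 5.64), EVI2B (5.17 and 5.49), the phosphatase gene DUSP2 (5.12 and 5.48) and CYP4X1 (4.85 and 4.54). EVI2B (log2 intensity 0.41), ZDHHC8BP (2.13) and DUSP2 (2.40) were dim on the TGFbeta Dox array, so the sizes and order of their differences depend on the floor. NPW was at the floor there, so its differences depend on the floor. With an offset of 16 they were 2.51 and 2.92, and with a variance trend and robust fit they did not pass (adjusted p = 0.647 and 0.591). Levels were lower with Snail and Zeb1 than with TGFbeta for TTC9 (-4.59 and -5.24) and SEMA7A (-4.41 and -4.04). Against the reference arrays TTC9 fell with Snail and Zeb1. SEMA7A instead rose with TGFbeta by 4.07 (1.46 by another probe set) and differed by -0.345 with Snail and 0.023 with Zeb1. EVI2B fell with TGFbeta and differed from the reference arrays by -0.347 with Snail and -0.03 with Zeb1. Among the 5 lowest with Snail were also KRT16 (-4.97), RAB3B (-4.39) and the glycosyltransferase B3GNT6 (-4.25), which did not pass with Zeb1 (-3.42, -2.38 and -2.57). Among the 5 lowest with Zeb1 were HMGN2P46 (-4.54), GPR17 (-4.48) and SERINC2 (-4.18). GPR17 (-3.58) and SERINC2 (-3.22) also passed with Snail (adjusted p = 0.0307 each), and HMGN2P46 (-2.81) did not. In all 196 genes differed between Snail and TGFbeta, 102 higher and 94 lower with Snail, and 220 between Zeb1 and TGFbeta, 99 higher and 121 lower with Zeb1. Each side is a single array, so a driver's effect cannot be told from that of an unusual culture. The counts rest on few arrays: without Vector Dox they were 2 and 3, without Vector 4 and 32, without Snail 26 and 34, without TGFbeta 111 and 120, and without the filter on dim probe sets 1 and 2. They rose to 519 and 519 with the filter at the 75th percentile, and to 610 and 605 with a variance trend and robust fit. With median centring the median of all genes in the Snail and TGFbeta comparison was 0.12, against 0.04 as reported, and 113 genes passed, 76 higher and 37 lower.

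By list, interferon genes were higher with Snail than with TGFbeta by a median of 2.13 (adjusted p = 2.2e-13; adjusted p = 0.0486 with an estimated correlation) and with Zeb1 by 1.90 (adjusted p = 9.8e-13; adjusted p = 0.073 with an estimated correlation). Integrated stress response genes were higher by 0.85 (adjusted p = 8.63e-08; adjusted p = 0.0486 with an estimated correlation) and by 0.96 (adjusted p = 3.64e-08; adjusted p = 0.073 with an estimated correlation). Cell cycle genes were higher by 0.87 (adjusted p = 2.72e-06; adjusted p = 0.295 with an estimated correlation) and by 0.89 (adjusted p = 9.8e-06; adjusted p = 0.342 with an estimated correlation), and cytokine genes with Zeb1 by 0.77 (adjusted p = 0.0388; adjusted p = 0.184 with an estimated correlation). Junction genes had medians of -1.04 with Snail (adjusted p = 7.2e-11; adjusted p = 0.163 with an estimated correlation) and -1.12 with Zeb1 (adjusted p = 1.4e-12; adjusted p = 0.136 with an estimated correlation). Epithelial keratins and identity genes had -0.90 (adjusted p = 1.76e-09; adjusted p = 0.163 with an estimated correlation) and -1.14 (adjusted p = 1.11e-10; adjusted p = 0.136 with an estimated correlation). Ligands had -0.84 (adjusted p = 1.51e-06; adjusted p = 0.0486 with an estimated correlation) and -0.76 (adjusted p = 6.85e-05; adjusted p = 0.073 with an estimated correlation). TGF-beta and SMAD targets had -0.62 (adjusted p = 0.0135; adjusted p = 0.242 with an estimated correlation) and -0.60 (adjusted p = 0.0279; adjusted p = 0.203 with an estimated correlation), and hypoxia genes -0.32 (adjusted p = 0.00148; adjusted p = 0.242 with an estimated correlation) and -0.45 (adjusted p = 0.00165; adjusted p = 0.203 with an estimated correlation). The remaining lists did not differ in the test.

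How far the responses overlap was read from the called genes and from each driver's difference from its own line. With each of the 3 drivers 54 genes rose, ZEB1 and SPARC among them, and 160 fell, FXYD3, TMPRSS4 and AGR2 among them. Snail and Zeb1 shared 135 rises and 326 falls, where independent calls would share 2.00 and 13.8, and had 0 calls in opposite directions. Snail and TGFbeta shared 61 rises and 186 falls against 4.67 and 18.4, with 10 opposite, ID3 among them, and Zeb1 and TGFbeta 60 and 192 against 4.21 and 21.1, with 5 opposite. For FXYD3 another probe set gave -0.505, -0.033 and -0.425 with Snail, Zeb1 and TGFbeta. The calls of all drivers use the same 5 reference arrays, so part of the sharing can come from them. As given below, it also stays open whether the Snail Dox and Zeb1 Dox arrays hold separate RNA or separate lines. That limit holds for each measure of their overlap, and for the shared response, which takes them as separate arrays. Differences from each driver's own line share no array. Across genes, which are not independent replicates, their correlation was 0.528 for Snail and Zeb1, 0.351 for Snail and TGFbeta and 0.314 for Zeb1 and TGFbeta, while the vector line's difference gave -0.007, 0.025 and -0.040 with Snail, Zeb1 and TGFbeta. Without the filter on dim probe sets the correlations between drivers were 0.280, 0.190 and 0.169. At least 2-fold from their own lines, Snail and Zeb1 shared 441 higher and 566 lower genes, where independence gives 75.4 and 91.5, Snail and TGFbeta 282 and 411 against 72.2 and 88.0, and Zeb1 and TGFbeta 305 and 426 against 88.1 and 104. In all 3 lines 174 genes were higher and 292 lower. Genes at least 2-fold apart in opposite directions numbered 112, 168 and 205. A split of the reference arrays gave too few calls to serve as a control.

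**Figure D3:**
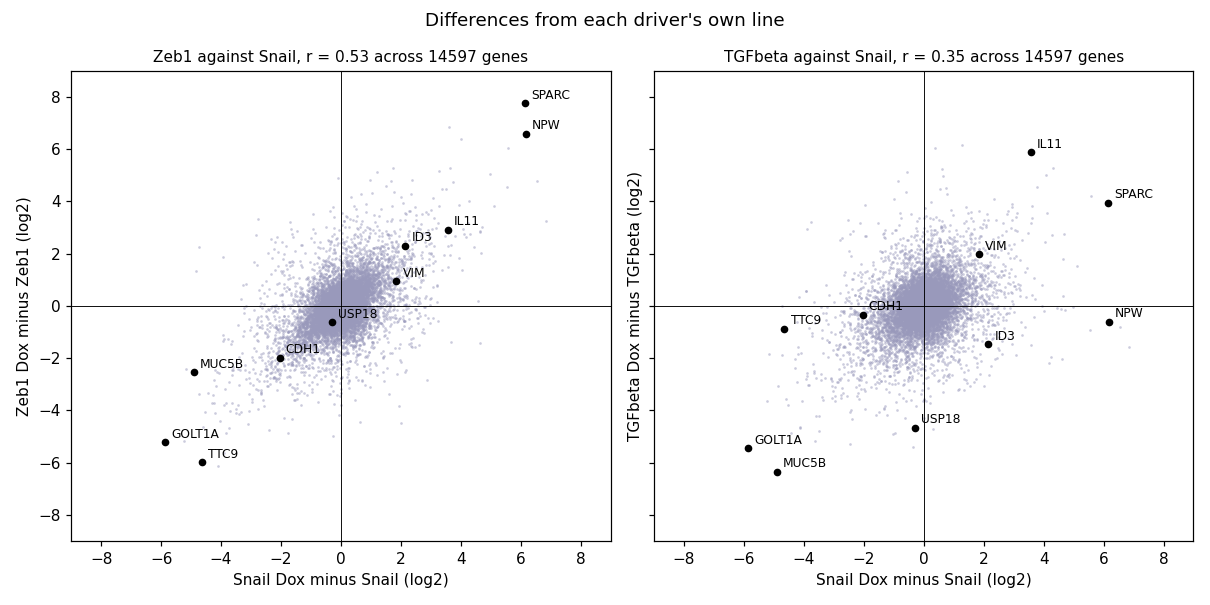
Log2 difference of each gene from its own line without doxycycline, 1 point per gene, for Zeb1 (left) and TGFbeta (right) against Snail, with some of the named genes marked. The Snail and Zeb1 differences have a correlation of 0.53 and the Snail and TGFbeta differences 0.35, or 0.280 and 0.190 without the filter on dim probe sets. Whether the Snail Dox and Zeb1 Dox arrays hold separate RNA or separate lines stays open.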

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

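The tests of interferon genes for drift and for scaling were chosen after the result was seen, as was brightness by the own pair of arrays. The rules of the other tests were written before. Those rules did not include the vector pair's probe set correlations or the run without probe sets whose names mark shared probes. Nor did they include the comparisons of Snail and Zeb1 with Vector, or of the TGFbeta line with Snail and Zeb1 alone.

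By correlation and SD of the difference, Snail Dox and Zeb1 Dox lay closer together than the Vector and Vector Dox arrays, although the Snail and Zeb1 lines without doxycycline lay apart. Among the brighter genes 11 lay at least 2-fold apart, against 10 in the vector pair. If Snail Dox and Zeb1 Dox held 1 RNA, probe sets of a gene should not share a difference between these arrays. Their correlation over 2892 genes was 0.189 (0.149 to 0.227), below the 0.322 of the vector pair but above 0. Without probe sets whose names mark shared probes, over 815 genes, it was 0.191 (0.118 to 0.259). The vector pair then had 0.255 (0.170 to 0.336), and the intervals overlap. A single RNA thus stays open. If both arrays came from 1 line, differences between the Snail and Zeb1 lines should be gone with doxycycline, and over 200 genes their correlation was 0.0852 (-0.0343 to 0.198), against 0.472 for the TGFbeta line against the other lines. That value is what a single line behind both arrays predicts. The same measure was 0.0631 between Snail and Vector and 0.120 between Zeb1 and Vector, so low values also occur between lines that the titles set apart. These are weak controls, since with doxycycline they set an induced driver against the vector. They also differed less without it, with 51 and 110 brighter genes at least 2-fold apart against 233 between Snail and Zeb1. Each line without doxycycline is 1 array, and differences of an array or culture rather than of a line would also give a low correlation. Snail and Zeb1 acting on the same genes stays open as an untested biological explanation.

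The list of interferon and antigen presentation genes was lower on the TGFbeta Dox array, although 15 of its 24 genes did not pass and the list did not pass with an estimated correlation (adjusted p = 0.0524). Its median log2 level there was 8.76, which is -0.56 from the lowest of the 5 uninduced arrays (9.32 to 9.91, SD 0.22), which argues against drift of the size seen among those arrays as the whole cause. Array scaling did not remove it, since the list's median change was -1.15 with the deposited scaling, -1.16 with median centring and -1.001 with an offset of 16. A lower interferon response under TGFbeta may be the biological explanation, as a hypothesis from 1 array, and a single unusual culture stays open.

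More of the called genes fell than rose with Snail and Zeb1, while among all genes at least 2-fold from the own line 950 rose and 1063 fell with Snail, and 1159 and 1257 with Zeb1. If the log scale of dim signals were the whole cause, an offset of 16 should bring rises near the number of falls, yet 33.9% of the 1433 Snail and Zeb1 calls were then rises, 35.6% with Snail and 32.2% with Zeb1. A noisy reference for dim genes should spare bright genes, and of the 1353 cases of a bright gene at least 2-fold from its own line 37.5% were rises, but 5 of the 8 arrays behind that brightness are uninduced, which favours falls. With brightness taken from the own pair of arrays, rises were 38.5% with Snail and 44.95% with Zeb1, so a noisy reference stays open. Repression by these factors also stays open, and TGFbeta gave 640 falls against 379 rises.

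In the test of the difference itself 196 genes differed between the Snail Dox and TGFbeta Dox arrays and 220 between Zeb1 Dox and TGFbeta Dox. Each side is 1 array, so a driver's effect cannot be told from that of an unusual culture. Zeb1 minus TGFbeta was -2.21 for CDH1, 2.24 for IL32, 3.48 for MUC5B, -3.90 for FAM201A, 6.80 for NPW, which was at the floor on the TGFbeta Dox array, 4.23 for ARC, -5.24 for TTC9, 3.60 for KIF21B, -4.48 for GPR17, 5.49 for EVI2B, 5.48 for DUSP2, -4.54 for HMGN2P46, -4.18 for SERINC2, -2.40 for LTBP2, -2.86 for PDGFA and 3.02 for SLC7A11 (log2). Snail minus TGFbeta was -3.28 for GPR160, -3.44 for MUC16, 3.87 for TMCO4, 3.52 for SECTM1, 4.29 for USP18, 2.13 for ADGRF1, 5.66 for ZDHHC8BP, 4.85 for CYP4X1, -4.97 for KRT16, -4.41 for SEMA7A, -4.39 for RAB3B and -4.25 for B3GNT6. It was also -2.95 for CLDN4, 2.69 for COL3A1, 4.03 for ID3, -3.15 for FGF1, -2.90 for CCND1, 2.92 for IFI44L, -2.14 for DSC2, 2.40 for FGFR3, 2.84 for OAS1 and 2.51 for PSMB9. Besides NPW, several of these genes were dim on 1 side. FAM201A (log2 intensity 0.33) and GPR17 (1.85) were dim on the Zeb1 Dox array. EVI2B (0.41), ZDHHC8BP (2.13) and DUSP2 (2.40) were dim on the TGFbeta Dox array. The sizes of such differences depend on the floor. Another MUC5B probe set gave -3.40 with Zeb1 and -2.28 with TGFbeta, so by it the difference goes the other way. With the filter at the 75th percentile 519 and 519 genes passed, with a variance trend and robust fit 610 and 605, without the filter on dim probe sets 1 and 2, without Vector Dox 2 and 3, without Vector 4 and 32, without Snail 26 and 34, and without TGFbeta 111 and 120.

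By list, the median of Snail minus TGFbeta was -1.04 for junction genes, -0.90 for epithelial keratins and identity, -0.62 for TGF-beta and SMAD targets, -0.84 for ligands, 0.87 for cell cycle, 2.13 for interferon, 0.85 for stress response and -0.32 for hypoxia genes. For Zeb1 minus TGFbeta the medians were -1.12, -1.14, -0.60, -0.76, 0.89, 1.90, 0.96 and -0.45 in the same order, and 0.77 for cytokine genes. With an estimated correlation 5 of the 8 list calls of Snail minus TGFbeta were lost, leaving interferon, stress response and ligands, and so were all 9 of Zeb1 minus TGFbeta.

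Among 104 named genes, 7 had an uninduced array far from the other 4, where chance gives about 1 in 20. On the Zeb1 array these were IL32 (log2 intensity 2.83), ODAPH (3.32) and TMCO4 (7.97), on the TGFbeta array RAB3B (4.97), MST1R (9.80) and CHAC1 (6.81), and on the Vector Dox array GPR17 (1.38). Hybridisation controls, which no comparison used, stood on the Zeb1 array at 1.90 times the median of the other arrays. Of 6495 probe sets without a single gene symbol, 132 passed in the shared response, 40 up and 92 down, from 6.57 to -4.12 (log2).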

How the results depend on the processing

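The deposited scaling, and the offset of 16 for the gene lists, were added after seeing the data. The planned quantile normalization is the setting reported, because the deposited values are linear. In the fits of the shared response, drivers and driver differences, all 7 counts stayed within 1.5 times with the deposited scaling, with the mean of a gene's probe sets and with probe sets tested singly. Of the 64 list results of the shared response and the drivers 46 were calls, and 31 of these were lost with an estimated correlation, as were 14 of the 17 list calls of the driver differences. With the deposited scaling, the offset of 16, the mean of probe sets, no filter and each uninduced array left out, 62 to 64 of the 64 stayed on the same side of the threshold. The lists were not run under the other settings. The 2-fold counts moved with the filter and the offset, so they depend on how dim probe sets are treated.

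Without the filter on dim probe sets, more genes are tested and dim probe sets enter. The counts became 885 for the shared response, 291 for Snail, 381 for Zeb1, 496 for TGFbeta, 1 for Snail and TGFbeta and 2 for Zeb1 and TGFbeta. Genes 2-fold apart became 2473 in the vector line and 2833, 3201 and 3072 between the Snail, Zeb1 and TGFbeta lines and Vector. The correlations between drivers fell to 0.280, 0.190 and 0.169, PDGFRA became -0.79 and FAM201A 0.056. With the filter at the 75th percentile the counts were 983 for Snail, 1 for Snail and Zeb1, and 519 for each driver against TGFbeta, and 2-fold genes 59 in the vector line and 128, 248 and 222 between lines. With log2 of the value plus 16 the 2-fold genes were 424, 562, 780 and 729.

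Median centring gave 113 genes for Snail and TGFbeta, and the cause was not tested. A variance trend with robust fit gave 1080, 1089 and 1628 for Snail, Zeb1 and TGFbeta and 610 and 605 for Snail and Zeb1 against TGFbeta, and the cause was not tested. An adjusted p under 0.01 gave 429 for the shared response, 137, 166 and 167 for the drivers, and 1 and 2 for the differences, and treat gave 206, then 174, 204 and 266, then 23 and 35, both being stricter. The line as a block gave 663 over all 8 arrays and, with fewer arrays, 0 in limma over the driver lines, where 2693 had an unadjusted p under 0.05. Of 185 calls of named genes, 92 were lost at an adjusted p under 0.01, 67 without the filter and 64 with treat. Leaving out Vector Dox lost 60, Vector 52, Snail 47, TGFbeta 31 and Zeb1 22. The mean of probe sets lost 22, a variance trend and robust fit 17, median centring 9, the deposited scaling 8 and the offset of 16 lost 3. Some settings were run for the shared response only, with 28 calls of named genes. The line as a block over the driver lines lost all 28 of these. Leaving out Snail Dox lost 2, leaving out Zeb1 Dox 1, and the line as a block over all 8 arrays 1.

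Leaving out arrays, which leaves fewer of them, gave 605 (without Snail Dox) to 2072 (without TGFbeta Dox) genes in the shared response, with 618 without Zeb1 Dox, 815 without Vector Dox, 848 without Vector and 924 without Snail. Leaving out uninduced arrays gave 270 (without Vector Dox) to 550 (without Zeb1) for Snail, 340 to 615 for Zeb1, 512 to 979 for TGFbeta, 2 to 143 for Snail and TGFbeta, 3 to 193 for Zeb1 and TGFbeta and 0 each time for Snail and Zeb1, where limma gave 417 at an unadjusted p under 0.05 with all arrays. CDH1 with TGFbeta was -0.33 against its own line and -0.17 with the mean of probe sets. It turned to 0.0085 with the deposited scaling, and ran from -0.056 (without Zeb1) over 0.014 (without Vector Dox) to 0.080 (without TGFbeta). TGFB3 with TGFbeta ran from -0.036 (without TGFbeta) to 0.14 (without Vector Dox).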

Other observations

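The test of gene families was chosen after the results of the lists were seen, and the count of splits before. Genes grouped by the stem of their symbol, 233 groups with at least 8 measured members, gave a few families, and some members of the MCM, PSMB, collagen and keratin families are also in the lists. Protocadherins of the beta cluster (PCDHB), cell adhesion proteins, had 8 rises and 0 falls among 15 in the shared response, with a median of 0.77 (log2; adjusted p = 6.88e-05), PCDHB15 by 1.24 and PCDHB13 by 0.91. Their medians were 0.83 with Snail (adjusted p = 0.00167), 0.75 with Zeb1 (adjusted p = 0.00535) and 0.82 with TGFbeta (adjusted p = 0.0166). Fucosyltransferases (FUT), which add fucose to surface glycans, had 4 falls and 0 rises among 8 in the shared response, with a median of -0.89 (adjusted p = 0.00973), FUT2 by 1.49, FUT9 by 2.04 and FUT3 by 1.37. Their medians were -0.91 with Snail (adjusted p = 0.00208), -1.19 with Zeb1 (adjusted p = 0.00535) and -0.46 with TGFbeta, which did not pass (adjusted p = 0.349).

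Replication genes of the MCM family had 6 falls and 0 rises among 11 with TGFbeta, with a median of -0.85 (adjusted p = 0.00891), and proteasome beta subunits (PSMB) had 3 falls among 11, with a median of -0.33 (adjusted p = 0.012). Neither family passed with Snail (adjusted p = 0.814 and 0.703) or Zeb1 (adjusted p = 0.736 and 0.59). Collagens (COL) had 6 rises and 1 fall among 31 in the shared response, with a median of 0.92 (adjusted p = 0.0252). Their medians were 0.77 with Snail (adjusted p = 0.0264), 1.01 with Zeb1 (adjusted p = 0.0268) and 0.52 with TGFbeta, which did not pass (adjusted p = 0.35). Keratins (KRT) had 6 falls and 0 rises among 23 with Zeb1, with a median of -0.52 (adjusted p = 0.0176), passed with Snail (adjusted p = 0.0455), and had 1 rise and 3 falls with TGFbeta (adjusted p = 0.992). BBS genes of the primary cilium had 2 rises among 8 in the shared response, with a median of 0.58 (adjusted p = 0.0143). BBS genes had medians of 0.59 with Snail (adjusted p = 0.0449), 0.58 with Zeb1 (adjusted p = 0.0268) and 0.46 with TGFbeta, which did not pass (adjusted p = 0.349). Differences between drivers were not tested for families. These tests used camera with its preset correlation, adjusted over the 233 families, and were not repeated with an estimated correlation.

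Of the 56 splits of the 8 arrays into 3 and 5, only 1, the real split, gave as many as 1433 genes in the shared response. The highest of the others gave 1. Every other split mixes induced and uninduced arrays within a group, which widens the spread, so few calls would be likely there. The arrays are also paired by line, so the count of splits does not exclude chance. Of the 32 splits that part as many lines, again only 1 gave as many. Exchanges within the driver lines make 8 arrangements, too few for a share under 0.05, and with the line as a block over these lines 0 genes passed, where 2693 had an unadjusted p under 0.05.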
